A study of Mus musculus with 8 samples.

How the data were processed

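The deposited values were FPKM per transcript, computed by the authors with Cufflinks 2.2.1 on reads aligned by HISAT2 to GRCm38.p6, per the submitters' processing notes. Cells were mouse embryonic fibroblasts, RNA was extracted with an RNeasy kit and libraries were made with a TruSeq stranded mRNA kit, per the labels' protocols. The counting is not stated to use the strand, so genes that overlap another gene on the opposite strand, such as Hoxa11os and Hand2os1, are uncertain. No read counts were used here, and all values start from FPKM. The unit was checked from the values: low values of a library lay on steps of whole fragments per kilobase. Depth and mean fragment length were fitted to these low values to bring them closest to whole numbers. With the fit, 91.2 to 94.0% of 311 to 349 low values per library lay within 0.1 of a whole number. By chance 20.0% would for a unit that was not fitted, so 20.0% is not the chance level of the fit.

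Each file held 142869 transcripts, whose FPKM values were summed to 55358 genes by the gene name given in the file. Classes and coordinates came from GENCODE M21 on GRCm38, in which 97.17% of transcript names and 53458 genes were found, 997 genes were classed by RefSeq, and 903 were matched to neither. Of 12716 lncRNA genes in the files, 671 were tested. Genes at 1 FPKM or more in at least 2 of the 8 libraries were kept (13693). Total FPKM per library was 561948, 553967, 575698, 584995, 536816, 540134, 537856 and 548429, and mitochondrially encoded genes held 1.303 to 2.163% of it. No pair of libraries held the same values.

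The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean per group over all 8 libraries, 4 residual degrees of freedom, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over the genes of a comparison. A result passed at an adjusted p below 0.05. The comparisons were IL-6 against none in WT and in KO, KO against WT without and with IL-6, and the difference between the IL-6 changes. Because the files held FPKM, the test for this unit was used, as the written design provides. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 43 of 45 lists with at least 3 genes tested; no list call in any comparison held with an estimated correlation. Macrophage markers had 2 genes tested and erythroid markers 1, too few for a list test. Shares of lncRNAs were compared by Fisher's exact test, adjusted over the 5 comparisons. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

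Test, lists, alternatives and the rule for named genes were fixed before the data were examined. In each comparison the text names the study's own genes, Arid5a first; of the called genes whose 2 libraries of a group both lay above both of the other and whose higher group had a mean of at least 1 FPKM, the 8 with the largest rise and the 8 with the largest fall; the 5 highest and 5 lowest lncRNAs in the same way; up to 4 members with the smallest p of each list that passed; and, with fewer than 5 calls, the 5 genes with the smallest p. Some members under this rule are left to the tables, and some genes the rule names are not reported here. The mesothelial and limb marker lists, Wt1, Cdkn2a, and Il6ra and Il6st without IL-6 were chosen after values were seen, and 18 list symbols were matched through RefSeq synonyms after a first look at the results, which brought the testable lists from 42 to 43.

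The procedure was tried on simulated values. Each gene had the same mean in all 8 libraries, taken from the data, and random noise of the fitted spread. These values held no genotype difference, unlike the data. Changes in WT with IL-6 were added to 50 genes of each size. Log2 changes of 0.25, 0.5, 1 and 2 were recovered in 16.0, 80.0, 100.0 and 100.0% for IL-6 in WT (10 unchanged genes called), in 4.0, 54.0, 94.0 and 100.0% for the difference between responses (7), and in 20.0, 80.0, 98.0 and 100.0% for KO against WT with IL-6 (12). With camera, a raised list had adjusted p = 2.82e-47 and 0 of 30 others passed. Noise was independent between genes, so this trial could not show false list calls that arise from correlated genes. Simulations of no effect and of equal responses used 20 draws each with the spread of the fit.

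Alternatives planned beforehand were quantile normalization, no intensity trend, no filter, a filter of 5 FPKM, pseudocounts of 0.1 and 5, the replicate number as a block, a fit of only the groups compared, leaving out each library, transcripts in place of genes, and for lists an estimated correlation and fry. Scaling each library to the same total FPKM and scaling by median ratios over genes of at least 5 FPKM were added after seeing the data. For single named genes only quantile normalization, the pseudocount of 0.1, the block and leaving out each library had been planned.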

Results

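RNA was sequenced from mouse embryonic fibroblasts, connective-tissue cells grown from embryos, wild type (WT) or labelled as Arid5a knockout (KO), each kept for 24 h without or with 100 ng/ml interleukin 6 (IL-6). Arid5a is an RNA-binding protein that stabilizes selected inflammatory transcripts, and the series was set up to find long non-coding RNAs (lncRNAs) of the IL-6 and Arid5a pathway with breast cancer in view. Its labels name the lncRNA AU021063, the pseudokinase gene Trib3 and the Mek/Erk kinases. Each of the 4 groups had 2 libraries (n = 2), and the data held were FPKM values of 142869 transcripts per library, summed here to 55358 genes. Small values lay on regular steps, from which a depth of 40.5 and 43.4 (untreated WT), 38.4 and 40.0 (WT with IL-6), 36.6 and 40.9 (untreated KO) and 40.8 and 47.1 (KO with IL-6) M fragments (M, 1e6) was read. In each library 12570 to 12699 genes reached 1 FPKM, and libraries of 1 group correlated at 0.9927 to 0.9935 across genes on the log2 scale. Levels are FPKM as mean ± SD over 2 libraries, changes are log2 differences ± SE of FPKM + 1 and so understate the fold of low genes, and 13693 genes were tested. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

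Arid5a itself (chromosome 1, 36307733 to 36324029, plus strand) stood at 18.73 and 15.89 FPKM in the untreated WT libraries, 30.86 and 30.99 in WT with IL-6, 5.51 and 6.853 in untreated KO, and 8.474 and 8.146 in KO with IL-6. IL-6 raised it in WT by 0.81 ± 0.10 (adjusted p = 0.0024). In KO the change of 0.38 ± 0.10 did not pass (adjusted p = 0.437), but neither did the difference between these changes. KO libraries held 35.7% of the WT level without IL-6 (-1.35 ± 0.10, adjusted p = 1.32e-05) and 26.9% with it (-1.78 ± 0.10, adjusted p = 2.67e-06). The loss differed between its transcripts: Arid5a-205, annotated as subject to nonsense-mediated decay, was at 8.77 ± 1.24 FPKM in untreated WT and 0.0943 ± 0.00271 in untreated KO, or 0.69% over both conditions, while Arid5a-204 kept 41.30%. Arid5a-207 kept 2.83%. The low Arid5a-208 was at 148.23%, with 0.408 ± 0.0183 FPKM in untreated WT and 0.805 ± 0.228 in untreated KO. Arid5a-211, a short transcript of exons 1 to 3 ending at position 36317442, was listed at 0 in WT and at 1.96 ± 0.651 FPKM in untreated KO. Which part of the gene was removed is not given in the labels.

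AU021063 (chromosome 15, 101221247 to 101222155, plus strand; 3 exons, 583 nt), the lncRNA named by the series, was near the detection limit. It was at 0.41 and 0.33 FPKM in untreated WT, 1.45 and 0.70 in WT with IL-6, listed at 0 in both untreated KO libraries, and at 0 and 0.13 in KO with IL-6. These values stand for about 6.73, 5.7, 25.89, 11, 0, 0, 0 and 2.27 fragments, and the gene lay under the expression filter. Without that filter, AU021063 was lower in KO with IL-6 by log2 -0.94 (adjusted p = 0.00649). In that setting 10988 of 27452 genes passed between KO and WT with IL-6. The untreated genotype difference of AU021063, -0.46 (adjusted p = 0.0884), and its IL-6 change in WT of 0.57 (adjusted p = 0.138) did not pass. Nor did the difference between its IL-6 changes, -0.49 (adjusted p = 0.456). Trib3, a pseudokinase induced by amino-acid and ER stress, was at 4.44 ± 0.163 FPKM in untreated WT and 17.6 ± 1.27 in untreated KO (1.77 ± 0.073, adjusted p = 4.23e-07), and with IL-6 it was higher in KO by 1.54 ± 0.073 (adjusted p = 8.57e-07). Its changes with IL-6 were -0.03 ± 0.073 in WT (adjusted p = 0.846) and -0.26 ± 0.073 in KO (adjusted p = 0.465).

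The Mek kinase genes were lower in KO. For these genes as for Trib3, most genes tested differed between the genotypes, 70.96% without IL-6 and 71.66% with it. Sex and tissue markers differed too, so these differences, and that of AU021063, cannot be assigned to Arid5a from these libraries. Map2k1, which encodes Mek1, was at 62.4 ± 0.527 FPKM in untreated WT and 52.9 ± 1.56 in untreated KO (-0.23 ± 0.037, adjusted p = 0.000816), and Map2k2, which encodes Mek2, at 139.6 ± 15.7 and 90.4 ± 5.90 (-0.62 ± 0.093, adjusted p = 0.000621). Erk1, from Mapk3, differed by -0.15 ± 0.046 (adjusted p = 0.0221; 0.11 without untreated WT library 1, 0.135 without untreated KO library 1). IL-6 changed Map2k1 in WT by 0.16 ± 0.037 (adjusted p = 0.0306), a call that ended without any 1 of the 4 WT libraries (0.0857 to 0.125) or either KO library with IL-6 (0.0535 and 0.0534). The Map2k1 call also ended with quantile normalization (0.11, adjusted p = 0.144) or equal totals (0.10, adjusted p = 0.153). No trend (0.0694), the replicate block (0.0527) or only the WT groups (0.0721) ended the Map2k1 call too. The Mapk3 call ended with equal totals (-0.10, adjusted p = 0.0601). The changes of Map2k2 (0.05) and Mapk3 (0.01) did not pass.

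**Figure D1:**
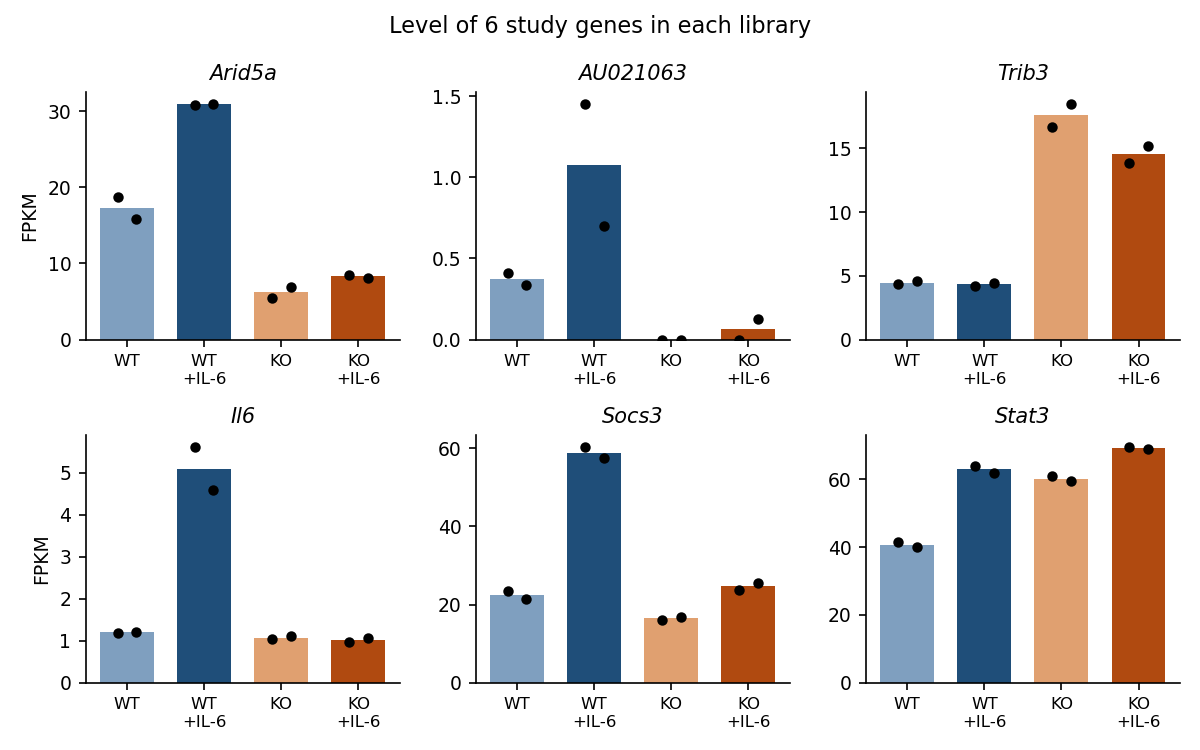
FPKM of 6 genes named by the study or central to IL-6 signalling, with bars at the mean of 2 libraries and points for each library of untreated WT, WT with IL-6, untreated KO and KO with IL-6 (linear axes from 0). Il6 was at 1.20 and 5.10 FPKM in WT without and with IL-6, and at 1.07 and 1.02 in KO.

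In WT fibroblasts, genes raised by 24 h of IL-6 included acute-phase genes. Saa3, an acute-phase serum amyloid, rose from 138.3 ± 6.29 to 594.5 ± 48.3 FPKM (2.09 ± 0.096, adjusted p = 3.31e-05), and Lcn2, which encodes the iron-siderophore carrier lipocalin 2, from 57.8 ± 1.38 to 215.0 ± 19.8 (1.87 ± 0.12, adjusted p = 0.000107). Hp, encoding haptoglobin, rose from 1.03 ± 0.373 to 8.27 ± 0.221 (2.21 ± 0.12), Kng1, encoding kininogen, from 1.70 ± 0.198 to 12.2 ± 1.11 (2.29 ± 0.11), and Fabp4, a fatty-acid carrier of fat cells, from 6.94 ± 0.717 to 30.8 ± 2.64 (2.0 ± 0.11). The protease inhibitor gene Serpina3n rose from 3.27 ± 0.112 to 24.4 ± 1.52 FPKM (2.57 ± 0.079, adjusted p = 1.72e-05), and the neighbouring pseudogene Serpina3e-ps fell (-2.58 ± 0.096); these near-identical copies can share fragments, so both values are uncertain. U90926, a short transcript induced in myeloid inflammation (2.32 ± 0.092), and the glutathione transferase gene Gstt4 (2.11 ± 0.17) also rose. Il6 rose from 1.20 ± 0.0177 to 5.10 ± 0.723 FPKM (1.46 ± 0.10, adjusted p = 0.000129), the transcription factor gene Stat3 from 40.7 ± 0.922 to 62.9 ± 1.31 (0.62 ± 0.037, adjusted p = 8.03e-05), and the feedback inhibitor gene Socs3 from 22.5 ± 1.44 to 58.9 ± 2.0 (1.35 ± 0.060, adjusted p = 2.87e-05).

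Falling genes included Acta2, smooth-muscle actin, from 45.4 ± 1.10 to 16.4 ± 0.999 FPKM (-1.41 ± 0.052, adjusted p = 1.97e-05), and Gdf7, a BMP-family ligand, from 17.6 ± 0.460 to 3.94 ± 0.159 (-1.91 ± 0.074). Hpgd, which degrades prostaglandins, fell from 5.94 ± 0.218 to 0.644 ± 0.00427 (-2.08 ± 0.10), and the collagen gene Col8a2 (-1.83 ± 0.071) and the Wnt antagonist gene Sfrp2 (-1.34 ± 0.13) fell as well. Vaultrc5, a vault RNA, was listed at 0 in both WT libraries with IL-6 (adjusted p = 0.0451), and Rpl39-ps, a copy of a ribosomal protein gene whose fragments are ambiguous, fell (-1.66 ± 0.31, adjusted p = 0.0128). Vaultrc5 failed without any 1 of the 4 WT libraries (0.145 to 0.149), and Rpl39-ps without untreated library 2 or either library with IL-6 (0.0621 to 0.0678). In all, 2150 of 13693 genes passed (15.70%; 1136 higher, 1014 lower; 3993 at unadjusted p below 0.05), of which 104 rose and 40 fell at least 2-fold on this scale. The number was 1312 and 1197 without untreated WT library 1 or 2, 1183 and 1165 without library 1 or 2 of WT with IL-6, 938 when only the WT libraries were fitted and 948 for transcripts. With each library scaled to the same total FPKM, 34.8% of calls were higher (818 higher, 1530 lower) against 52.8% as deposited.

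Gene lists fixed beforehand were tested next. Of the STAT3 list, 28 of 33 genes rose and 1 fell (29 past the threshold adjusted over the list alone, list adjusted p = 2.35e-23, but adjusted p = 0.179 with an estimated correlation). Members included Timp1, an inhibitor of matrix proteases (114.0 ± 1.91 to 337.1 ± 2.42 FPKM, 1.56 ± 0.034), the pentraxin gene Ptx3 (1.37 ± 0.047) and the cytokine receptor gene Il13ra1 (1.44 ± 0.060). Complement and acute-phase genes rose in 11 of 16 (13 adjusted over the list alone, list adjusted p = 9e-13, or 0.184 with an estimated correlation). Serping1, the C1 inhibitor, changed by 1.17 ± 0.060. Of IL-6 receptor and JAK/STAT genes, 11 of 22 rose and 2 fell (16 adjusted over the list alone, list adjusted p = 0.000737, or 0.26 with an estimated correlation). The oncostatin M receptor gene Osmr changed by 1.17 ± 0.050. Transcripts reported elsewhere as Arid5a targets rose in 4 of 6 (4 adjusted over the list alone, list adjusted p = 0.000737, or 0.179 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, was among them (1.16 ± 0.096). The list of study genes gave 5 of 9 rising (5 adjusted over the list alone, list adjusted p = 0.000328, or 0.179 with an estimated correlation).

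NF-kappaB targets rose in 10 of 17 and fell in 1 (12 adjusted over the list alone, list adjusted p = 5.03e-06, or 0.179 with an estimated correlation). The mitochondrial dismutase gene Sod2 changed by 1.03 ± 0.049 and the adhesion gene Vcam1 by -0.46 ± 0.050. Cytokines and chemokines rose in 11 of 21 and fell in 2 (15 adjusted over the list alone, list adjusted p = 0.00011, or 0.205 with an estimated correlation). The rising genes included Cxcl12, which guides stem and immune cells (0.57 ± 0.033), and the neutrophil attractant gene Cxcl2 (1.01 ± 0.069). Proteases and their inhibitors rose in 11 and fell in 1 of 23 (16 adjusted over the list alone, list adjusted p = 5.03e-06, or 0.179 with an estimated correlation). The collagenase gene Mmp13 changed by 1.5 ± 0.085 and stromelysin, Mmp3, by 1.30 ± 0.093. Hypoxia and glycolysis genes rose in 15 of 25 and fell in none (17 adjusted over the list alone, list adjusted p = 3.03e-09, or 0.225 with an estimated correlation). Both the lactate exporter gene Slc16a3 (0.79 ± 0.046) and the angiogenic factor gene Vegfa (0.56 ± 0.072) rose. Of immediate early genes, 8 of 17 rose and 1 fell (12 adjusted over the list alone, list adjusted p = 0.00112, or 0.179 with an estimated correlation). The AP-1 gene Junb changed by 1.22 ± 0.062. Growth factor and IGF genes rose in 11 and fell in 5 of 32 (19 adjusted over the list alone, list adjusted p = 0.0302, or 0.241 with an estimated correlation). Angptl4, a lipase inhibitor (1.64 ± 0.082), Ereg, an EGF receptor ligand (1.51 ± 0.076), and Igfbp3, an IGF carrier (1.5 ± 0.050), rose.

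Cytosolic ribosomal protein genes rose in 35 of 76 (median 0.15, 56 adjusted over the list alone, list adjusted p = 1.11e-16, or 0.205 with an estimated correlation). LncRNA hosts of snoRNAs rose in 9 of 18 (10 adjusted over the list alone, list adjusted p = 5.63e-05, or 0.179 with an estimated correlation). Snhg1, also a regulator of growth, was at 0.37 ± 0.067 (adjusted p = 0.0676 without library 2 of WT with IL-6), and the calls of the hosts Gas5, Snhg6 and Zfas1 ended without untreated WT library 1 (0.0906 to 0.1) or either WT library with IL-6 (0.0706 to 0.138). These 3 calls ended too with quantile normalization (0.0512 to 0.0863), equal totals (0.0658 to 0.0861) or no filter (0.0577 to 0.0979). Adipocyte markers rose in 3 of 4 (3 adjusted over the list alone, list adjusted p = 0.00349, or 0.205 with an estimated correlation), Fabp4 among them.

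Contractile and myofibroblast genes fell in 9 of 13 (median -0.34, 9 adjusted over the list alone, list adjusted p = 2.34e-09, or 0.205 with an estimated correlation). The actin-binding gene Tagln changed by -1.08 ± 0.062 and Ccn2, a connective-tissue growth factor, by -1.10 ± 0.066. Fibrillar matrix genes fell in 15 and rose in 7 of 36 (22 adjusted over the list alone, list adjusted p = 0.0302, or 0.57 with an estimated correlation). Thrombospondin, Thbs1, fell (-1.21 ± 0.048) and the proteoglycan gene Dcn rose (1.36 ± 0.081). Interferon-stimulated genes fell in 7 and rose in 2 of 43 (11 adjusted over the list alone, list adjusted p = 0.00308, or 0.674 with an estimated correlation). Of these calls, the rises of Irf1 and Gbp2, a transcription factor and a GTPase gene, and the fall of the antiviral gene Bst2 ended without untreated WT library 1 (0.0603 to 0.0876) or 2 (0.0635 to 0.0716). MHC class I genes fell in 3 of 13 (6 adjusted over the list alone, list adjusted p = 0.0385, or 0.622 with an estimated correlation). All 3 calls ended without untreated WT library 1 (0.0599 to 0.095) or 2 (0.0902 to 0.173), or library 2 of WT with IL-6 (0.0676 to 0.162). They ended too with no filter (0.072 to 0.151) or only the WT groups (0.081 to 0.138), and that of Psmb9 with the replicate block (0.0543). Wnt, BMP and hedgehog genes fell in 9 and rose in 4 of 20 (15 adjusted over the list alone, list adjusted p = 0.0326, or 0.32 with an estimated correlation). The Wnt antagonist gene Dkk2 fell (-1.16 ± 0.087) and Sfrp1, another antagonist gene, rose (1.17 ± 0.071). Targets of p53 fell in 6 and rose in 2 of 21 (9 adjusted over the list alone, list adjusted p = 0.031, or 0.205 with an estimated correlation). The kinase gene Plk2 changed by -0.86 ± 0.054. Imprinted genes fell in 3 of 12 (5 adjusted over the list alone, list adjusted p = 0.0253, or 0.225 with an estimated correlation). Of these calls, those of the lncRNA H19 and the receptor gene Igf2r ended without untreated WT library 2 (0.0764 and 0.107) or either WT library with IL-6 (0.0542 to 0.102). Grb10, a growth-factor receptor adaptor, changed by -0.27 ± 0.039. Replication histone genes, which poly(A) selection mostly misses, fell in 2 of 3 (2 adjusted over the list alone, list adjusted p = 0.033, or 0.234 with an estimated correlation). The call of the histone gene H2aw ended without any 1 of the 4 WT libraries (0.0992 to 0.184) or either untreated KO library (0.071 and 0.0711). The H2aw call ended too with a pseudocount of 0.1 (0.057), the replicate block (0.0693), no trend (0.051) or no filter (0.12).

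Of lncRNAs in WT, Gm48898, which lies next to Gdf7 on the same strand of chromosome 12 (8291024 to 8293694), fell from 32.8 ± 0.956 to 8.74 ± 0.352 FPKM (-1.79 ± 0.069, adjusted p = 1.97e-05). Gm6093 rose from 3.55 ± 0.432 to 12 ± 0.464 (1.51 ± 0.090, adjusted p = 7.46e-05) and Gm13293 from 0.433 ± 0.0678 to 2.79 ± 0.553 (1.40 ± 0.14, adjusted p = 0.000979), both without a known function. Gm37055, of 133 nt, was listed at 0 in untreated WT and at 7.37 ± 3.95 FPKM with IL-6 (adjusted p = 0.000562). The mean fragment lengths implied by the low values were 120 to 210 nt. Few fragments can thus make several FPKM of so short a gene, and its level is uncertain. Gm15655 (0.98 ± 0.17) and Gm15640 (0.96 ± 0.24) rose, and Gm37270 (-1.34 ± 0.23), Gm17501 (-0.83 ± 0.072), Gm42778 (-0.81 ± 0.11) and Zfp469, a zinc-finger locus classed as lncRNA (-0.90 ± 0.080), fell. The call of Gm15655 ended without untreated WT library 2 (0.0558), that of Gm37270 without untreated WT library 1 (0.0598) or library 2 of WT with IL-6 (0.0589), and that of Gm15640 without any 1 of 5 libraries (0.0612 to 0.17). The Gm15640 call ended too with a pseudocount of 0.1 (0.127), no trend (0.0517) or no filter (0.123). Of 671 lncRNA genes tested, 67 passed (33 higher, 34 lower), or 9.99% against 16.00% of other genes (odds ratio 0.583, 95% confidence interval 0.444 to 0.754; adjusted p = 2.13e-05, Fisher's exact test). At 5 FPKM or more the ratio lay on the other side of 1 (1.368, with 164 lncRNA genes).

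In KO fibroblasts, IL-6 raised 3 genes past the threshold and lowered none. Igfbp3, an IGF carrier protein gene, rose from 51.1 ± 0.401 to 93.7 ± 1.89 FPKM (0.86 ± 0.050, adjusted p = 0.0028), Spp1, encoding the matrix protein osteopontin, from 73.7 ± 0.483 to 110.4 ± 3.0 (0.58 ± 0.034, adjusted p = 0.0028), and Cebpd, an acute-phase transcription factor gene, from 6.70 ± 0.311 to 11.4 ± 0.523 (0.69 ± 0.063, adjusted p = 0.0401). Next by p were Osmr (16.7 ± 0.251 to 23.7 ± 0.332 FPKM, 0.49 ± 0.050, adjusted p = 0.0706) and Socs3 (16.5 ± 0.609 to 24.6 ± 1.11, 0.55 ± 0.060, adjusted p = 0.0774). Saa3 went from 5.37 ± 0.760 to 8.30 ± 0.704 FPKM (0.55 ± 0.096, adjusted p = 0.279), Stat3 from 60.2 ± 0.910 to 69.1 ± 0.50 (0.20 ± 0.037, adjusted p = 0.279) and Il6 from 1.07 ± 0.0510 to 1.02 ± 0.0757 (-0.04 ± 0.10, adjusted p = 0.974). No lncRNA of 671 passed, and 1025 genes were at unadjusted p below 0.05. The count of 3 became 1, a lower gene and so none of the 3, without untreated KO library 1. It was 4 (2 higher, 2 lower) without either library of WT with IL-6. It was 0 without untreated KO library 2 or when only KO libraries were fitted. No filter gave 7 and a filter of 5 FPKM gave 5, all higher. Transcripts gave 2, both lower. Cebpd failed without any 1 of the 8 libraries (adjusted p 0.0516 to 0.321), Spp1 and Igfbp3 without untreated KO library 1 or 2 (0.0551 and 0.0718), and Igfbp3 also without library 2 of KO with IL-6 (0.0524). Cebpd failed too with no filter (0.0733), no trend (0.0967) or a pseudocount of 5 (0.0659).

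STAT3 targets passed as a list in KO, though not with an estimated correlation. Of 33 genes, 1 rose over all genes tested and 19 passed adjusted over the list alone (median 0.24, list adjusted p = 3.21e-19, or 0.13 with an estimated correlation). Cebpb, a partner of Cebpd, had a change of 0.50 ± 0.060. Complement and acute-phase genes had a median of 0.24 (0 past the threshold, 10 adjusted over the list alone, list adjusted p = 1.42e-11, or 0.334 with an estimated correlation). The complement gene C4b had a change of 0.43 ± 0.097. Sterol synthesis genes had a median of -0.10 (0 past the threshold, 2 adjusted over the list alone, list adjusted p = 3.4e-09, or 0.13 with an estimated correlation). The sterol sensor gene Insig1 had a change of -0.17 ± 0.035. Targets of the integrated stress response, the pathway that induces Trib3, had -0.11 (0 past the threshold, 7 adjusted over the list alone, list adjusted p = 7.83e-09, or 0.334 with an estimated correlation). Its transcription factor gene Atf4 had a change of -0.15 ± 0.040. Interferon-stimulated genes had -0.12 (0 adjusted over the list alone, list adjusted p = 2.57e-06, or 0.66 with an estimated correlation).

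Further lists in KO with no member past the threshold passed as lists. Ribosomal protein genes had a median of 0.07 (list adjusted p = 3.9e-11, or 0.526 with an estimated correlation, 0 adjusted over the list alone) and mitochondrially encoded genes of 0.11 (list adjusted p = 0.00744, or 0.633 with an estimated correlation, 0 adjusted over the list alone). On the lower side stood fibrillar matrix (median -0.07, list adjusted p = 0.002, or 0.633 with an estimated correlation, 3 adjusted over the list alone) and p53 targets (median -0.07, list adjusted p = 0.00442, or 0.308 with an estimated correlation, 0 adjusted over the list alone). TGF-beta responses (median -0.07, list adjusted p = 0.0134, or 0.526 with an estimated correlation, 0 adjusted over the list alone) and hypoxia and glycolysis (median -0.06, list adjusted p = 0.0288, or 0.66 with an estimated correlation, 0 adjusted over the list alone) were lower too.

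The difference between the IL-6 responses (KO change minus WT change) was tested directly. Timp1 rose by 1.56 in WT and went from 157.8 ± 3.47 to 188.4 ± 1.93 FPKM in KO (difference -1.30 ± 0.048, adjusted p = 9.04e-05), and Ptx3 from 79.1 ± 1.57 to 80.6 ± 0.159 (-1.34 ± 0.066, adjusted p = 0.000365). Il6 differed by -1.5 ± 0.14 (adjusted p = 0.00186), Socs3 by -0.80 ± 0.085 (adjusted p = 0.00277) and Stat3 by -0.42 ± 0.052 (adjusted p = 0.00542), while Arid5a (-0.43 ± 0.15, adjusted p = 0.148) and Trib3 (-0.23 ± 0.10, adjusted p = 0.252) did not pass. Slpi, a leukocyte protease inhibitor gene, was at 6.25 ± 0.387 and 24.8 ± 2.17 FPKM in WT and 8.31 ± 0.463 and 7.91 ± 0.238 in KO (-1.89 ± 0.11), and Tnfsf11, encoding the osteoclast factor RANKL, at 0.900 ± 0.117, 4.31 ± 1.13, 0.658 ± 0.178 and 0.337 ± 0.0373 (-1.77 ± 0.22). Acta2, which fell in WT, stood at 341.4 ± 13.2 and 322.1 ± 9.50 FPKM in KO (1.33 ± 0.074, adjusted p = 0.000365), and Col8a2 at 44.6 ± 0.240 and 35.4 ± 1.80 (1.5 ± 0.10). For Serpina3n (-2.51 ± 0.11, copies uncertain), U90926 (-2.32 ± 0.13), Kng1 (-2.25 ± 0.16), Fabp4 (-2.04 ± 0.15), Gdf7 (1.91 ± 0.10), Hpgd (2.06 ± 0.15) and Gm48898 (1.81 ± 0.097), KO means lay below 0.2 FPKM in both conditions. Of lncRNAs, Gm13293 (-1.44 ± 0.20) and Gm15867 (1.17 ± 0.19), of unknown function, differed as well, the latter with 1.42 ± 0.162 and 0.474 ± 0.167 FPKM in WT and 2.32 ± 0.502 and 3.52 ± 0.346 in KO. The Gm15867 call ended without untreated WT library 1 (0.0584), library 1 of WT with IL-6 (0.0551) or library 2 of KO with IL-6 (0.0652).

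In all, 830 genes passed (6.06%; 348 with a higher and 482 with a lower change in KO; 2916 at unadjusted p below 0.05), 24 of them lncRNAs (17 and 7; 3.58% against 6.19% of other genes; odds ratio 0.562, 95% confidence interval 0.355 to 0.850; adjusted p = 0.00577, Fisher's exact test; 1.072 at 5 FPKM or more). The count was 523 and 442 without untreated WT library 1 or 2, 447 and 470 without library 1 or 2 of WT with IL-6, 430 and 383 without untreated KO library 1 or 2, and 409 and 396 without library 1 or 2 of KO with IL-6. It was 520 with no filter and 248 for transcripts, and the higher share, 41.9%, was 55.1% with equal totals (478 higher, 390 lower). Of the 1136 genes raised in WT, such as Saa3 and Timp1, the median change was 0.360 in WT and 0.030 in KO, 722 (63.6%) kept their sign, and 467 had a called difference toward 0, where independent lists would share 40.0. Among the 1014 lowered genes, such as Acta2, the medians were -0.363 and -0.023, 611 (60.3%) kept their sign, and 330 had a called difference toward 0 (25.8 for independent lists). Both tests use the same WT libraries: in simulations with no effect their values correlated at -0.704 (-0.760 to -0.655 over 20 draws), with 255.000 genes at unadjusted p below 0.05 in both and of opposite sign. Simulated equal responses gave a mean of 0.050 genes called in WT with a called difference toward 0 (0 to 1). The medians of genes raised in WT were 0.314 in WT and 0.276 in KO. That simulation started KO from the untreated WT levels, so it held no genes that were low in KO alone. It also called more genes in WT than the data did (3471.500 against 2150). Across genes, which are not independent replicates, the WT and KO changes had r = -0.037 (rho 0.088), and 3 genes were called in both (0.25 by chance).

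**Figure D2:**
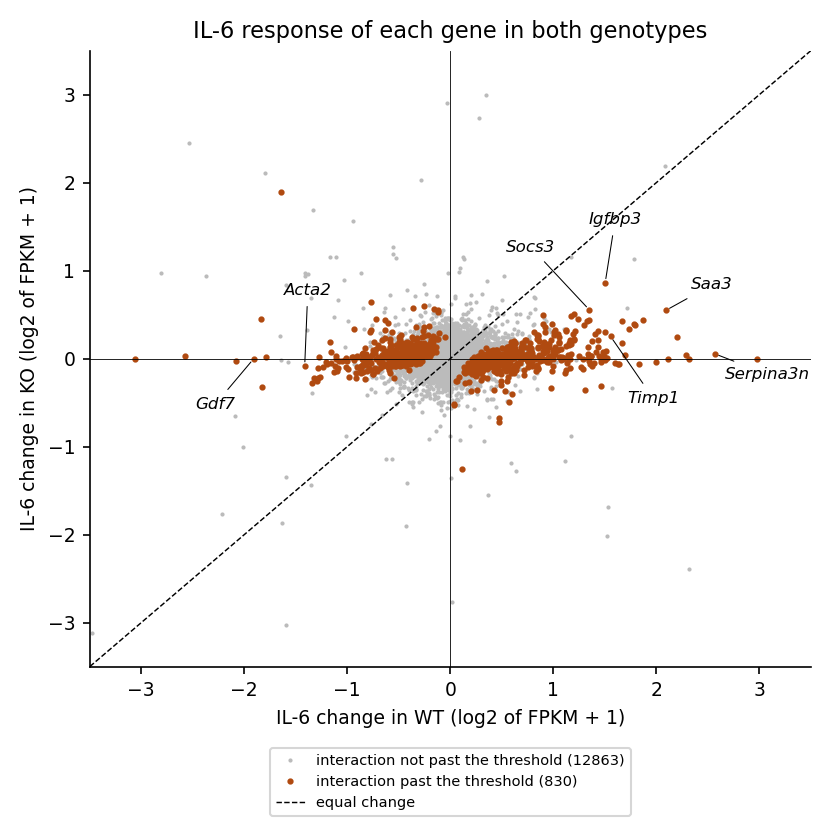
Log2 change of each tested gene with IL-6 in WT (x) and in KO (y), in FPKM + 1, with the 830 genes of a called difference between the genotypes in colour and a dashed line of equal change. 6 genes lie outside the drawn range of -3.5 to 3.5, and Timp1 is at 1.56 on x and 0.25 on y, Igfbp3, called in both, at 1.5 and 0.86.

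By list, the difference lay mostly below 0. STAT3 targets had 18 of 33 lower and 1 higher (24 adjusted over the list alone, list adjusted p = 7.64e-16, or 0.187 with an estimated correlation). Complement and acute-phase genes had 8 of 16 lower (12 adjusted over the list alone, list adjusted p = 3.48e-07, or 0.266 with an estimated correlation), Serping1 included (-0.95 ± 0.084). Cytokines and chemokines had 9 of 21 lower and 1 higher (15 adjusted over the list alone, list adjusted p = 5.83e-06, or 0.187 with an estimated correlation). NF-kappaB targets had 6 of 17 lower and 1 higher (10 adjusted over the list alone, list adjusted p = 1.08e-05, or 0.187 with an estimated correlation), and reported Arid5a targets 4 of 6 (5 adjusted over the list alone, list adjusted p = 0.00208, or 0.187 with an estimated correlation). IL-6 receptor and JAK/STAT genes had 9 of 22 lower (11 adjusted over the list alone, list adjusted p = 0.00144, or 0.338 with an estimated correlation), with Osmr at -0.69 ± 0.071. The study genes had 3 of 9 lower (5 adjusted over the list alone, list adjusted p = 3.1e-05, or 0.187 with an estimated correlation). Hypoxia and glycolysis had 11 of 25 lower (14 adjusted over the list alone, list adjusted p = 8.87e-10, or 0.238 with an estimated correlation), with Slc16a3 at -0.88 ± 0.066. Proteases and inhibitors had 10 of 23 lower and 1 higher (12 adjusted over the list alone, list adjusted p = 1.37e-05, or 0.187 with an estimated correlation), with Mmp13 at -1.20 ± 0.12. Contractile genes alone had a higher change in KO, 6 of 13 (10 adjusted over the list alone, list adjusted p = 1.53e-08, or 0.238 with an estimated correlation). Tagln differed by 1.05 ± 0.087.

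Targets of ERK, the kinases downstream of Mek, had 2 of 22 lower and 1 higher (6 adjusted over the list alone, list adjusted p = 0.0419, or 0.384 with an estimated correlation). The ERK phosphatase gene Dusp6 was at 5.20 ± 0.636 and 9.71 ± 0.612 FPKM in WT and 29.2 ± 1.63 and 28.7 ± 0.388 in KO (-0.82 ± 0.12, adjusted p = 0.00881), and Ccnd1, encoding cyclin D1, at 18.8 ± 0.591, 7.08 ± 0.542, 3.77 ± 0.0113 and 2.99 ± 0.0790 (1.04 ± 0.095, adjusted p = 0.00174). Integrated stress response targets had 5 of 31 lower and 1 higher (12 adjusted over the list alone, list adjusted p = 0.031, or 0.488 with an estimated correlation). Asns, asparagine synthetase, differed by -0.46 ± 0.065. Immediate early genes had 3 of 17 lower (8 adjusted over the list alone, list adjusted p = 0.00702, or 0.187 with an estimated correlation), with Junb at -0.90 ± 0.088. Growth factor and IGF genes had 7 of 32 lower and 2 higher (14 adjusted over the list alone, list adjusted p = 0.031, or 0.287 with an estimated correlation), with Angptl4 at -1.70 ± 0.12. Ribosomal protein genes had a small shift (median -0.09, 3 lower, 0 adjusted over the list alone, list adjusted p = 1.08e-05, or 0.397 with an estimated correlation), as did sterol synthesis genes (median -0.12, 0 lower, 0 adjusted over the list alone, list adjusted p = 0.00182, or 0.187 with an estimated correlation). For snoRNA hosts no gene passed (median -0.19, 0 lower, 0 adjusted over the list alone, list adjusted p = 0.00241, or 0.187 with an estimated correlation), and of adipocyte markers 1 did (median -0.34, 1 lower, 3 adjusted over the list alone, list adjusted p = 0.00843, or 0.238 with an estimated correlation).

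**Figure D3:**
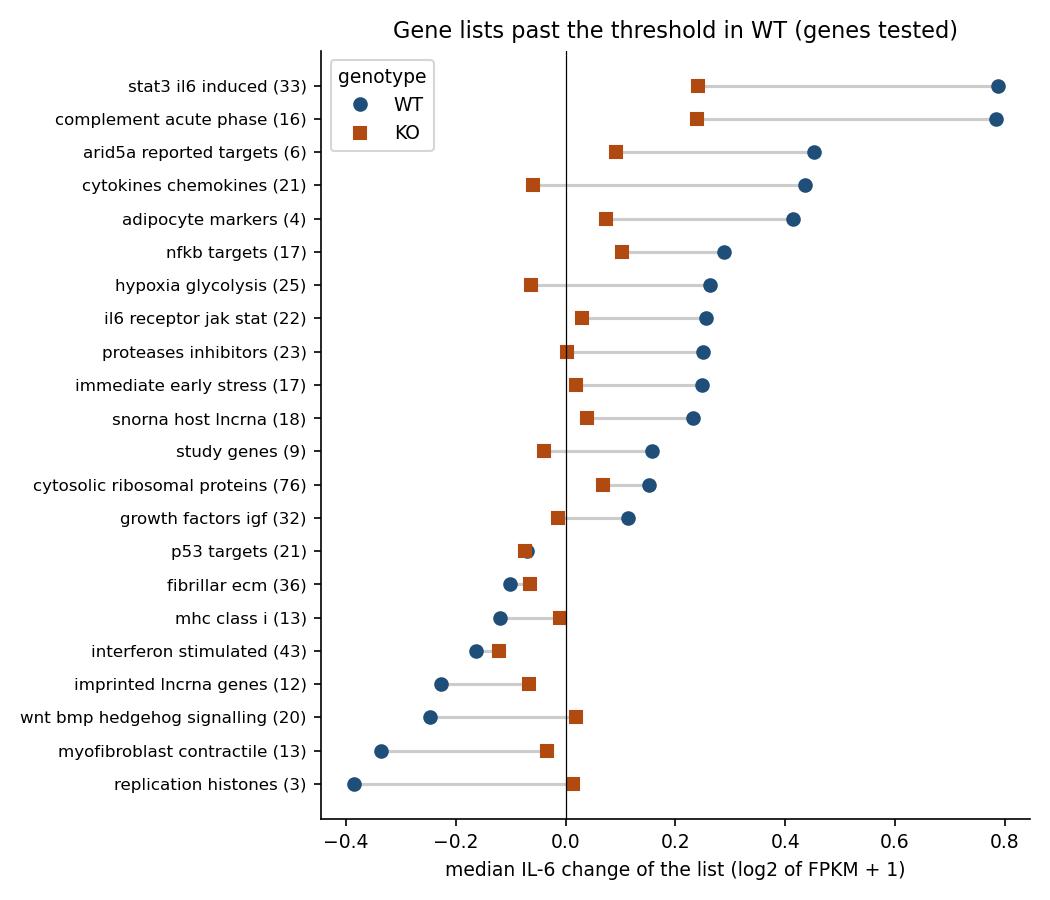
Median log2 change with IL-6 of the 22 gene lists past the list threshold in WT, for WT (circles) and KO (squares), in FPKM + 1, with the number of genes tested in brackets. The STAT3 list is at 0.79 in WT and 0.24 in KO, and contractile genes at -0.34 and -0.03.

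Without IL-6, most genes tested differed between the genotypes. Upk3b, a membrane protein of mesothelium and urothelium, was at 0.0356 ± 0.00168 FPKM in WT and 526.5 ± 11.5 in KO (8.99 ± 0.042, adjusted p = 2.74e-11). Its partner Upk1b was listed at 0 in WT and at 332.4 ± 8.00 in KO, and the transmembrane gene Lrrn4 at 0 and 180.5 ± 0.942. Trf, encoding the iron carrier transferrin, was listed at 0 in WT and at 1368 ± 12 FPKM in KO, Rhox5, an X-linked homeobox gene, at 0 and 662.0 ± 2.90, and Tspan8, a tetraspanin gene of epithelia, at 0 and 129.5 ± 2.94. Gpm6a, a membrane glycoprotein of neurons and mesothelium, was at 284.1 ± 2.53 in KO (8.15 ± 0.043), and Aldh1a1, a retinoic acid enzyme, at 284.1 ± 1.09 (7.96 ± 0.049). Lower in KO were Crabp1, a retinoic acid carrier of embryonic mesenchyme, at 623.4 ± 11.7 in WT and 0.147 ± 0.0971 in KO (-9.09 ± 0.084, adjusted p = 3.86e-10), the chemokine gene Cxcl5 (714.6 ± 20.6 and 0.535 ± 0.118, -8.87 ± 0.068) and Ly6a, the stem-cell antigen Sca-1 (610.6 ± 12.4 and 1.95 ± 0.986, -7.74 ± 0.23). Further down were the Wnt-induced matrix gene Ccn5 (-7.98 ± 0.095), the opioid precursor gene Penk (-7.87 ± 0.059), the matrix gene Aspn (-7.67 ± 0.047), Enpp2, which makes lysophosphatidic acid (-7.10 ± 0.057), and the lipid carrier gene Apod (-7.01 ± 0.16).

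Sex-linked genes lay on opposite sides. Xist, the lncRNA of the inactive X chromosome, was at 0.00329 ± 0.00269 FPKM in WT and 56.9 ± 2.44 in KO (5.85 ± 0.059, adjusted p = 4.8e-10). The Y-linked gene Eif2s3y, for translation, was lower in KO (-5.90 ± 0.059), and Ddx3y (35.6 ± 1.46 FPKM in WT) and Kdm5d (10.9 ± 0.278), an RNA helicase and a histone demethylase gene, were listed at 0 there, with 4 of 5 members lower (5 adjusted over the list alone, list adjusted p = 0.0493, or 0.449 with an estimated correlation). Hox genes, which record position along the body, were lower in 25 and higher in 7 of 32 (32 adjusted over the list alone, list adjusted p = 5.57e-05, or 0.307 with an estimated correlation). Hoxc10, a hindlimb gene, was at 48.8 ± 0.282 and 0.0662 ± 0.00572 FPKM (-5.55 ± 0.054), and Hoxa11, a limb gene, differed by -4.41 ± 0.063. Epithelial and keratinocyte markers were higher in 8 and lower in 1 of 9 (9 adjusted over the list alone, list adjusted p = 0.00109, or 0.307 with an estimated correlation). Of the keratin genes, Krt7 differed by 5.14 ± 0.064 and Krt19 by 5.17 ± 0.091. EMT regulators were lower in 9 and higher in 2 of 11 (11 adjusted over the list alone, list adjusted p = 0.0219, or 0.353 with an estimated correlation). The mesenchymal homeobox gene Prrx1 differed by -3.07 ± 0.055. In marker lists chosen after these values were seen, 10 of 10 mesothelial genes were higher in KO (of all genes tested, 36.4% were), such as the transcription factor genes Bnc1 (5.90 ± 0.078) and Gata6 (5.92 ± 0.056). Of limb genes, 8 of 8 were lower (of all genes tested, 34.5% were), such as the homeobox genes Shox2 (-4.44 ± 0.054) and Alx4 (-4.37 ± 0.067). In each of these lists 3 genes had been seen in earlier lists. The list of limb and positional transcription factors fixed beforehand had 12 lower and 7 higher of 21 and did not pass (list adjusted p = 0.103). Wt1, a mesothelial transcription factor gene also chosen after its values were seen, was listed at 0 in WT and at 111.3 ± 3.03 FPKM in KO.

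**Figure D4:**
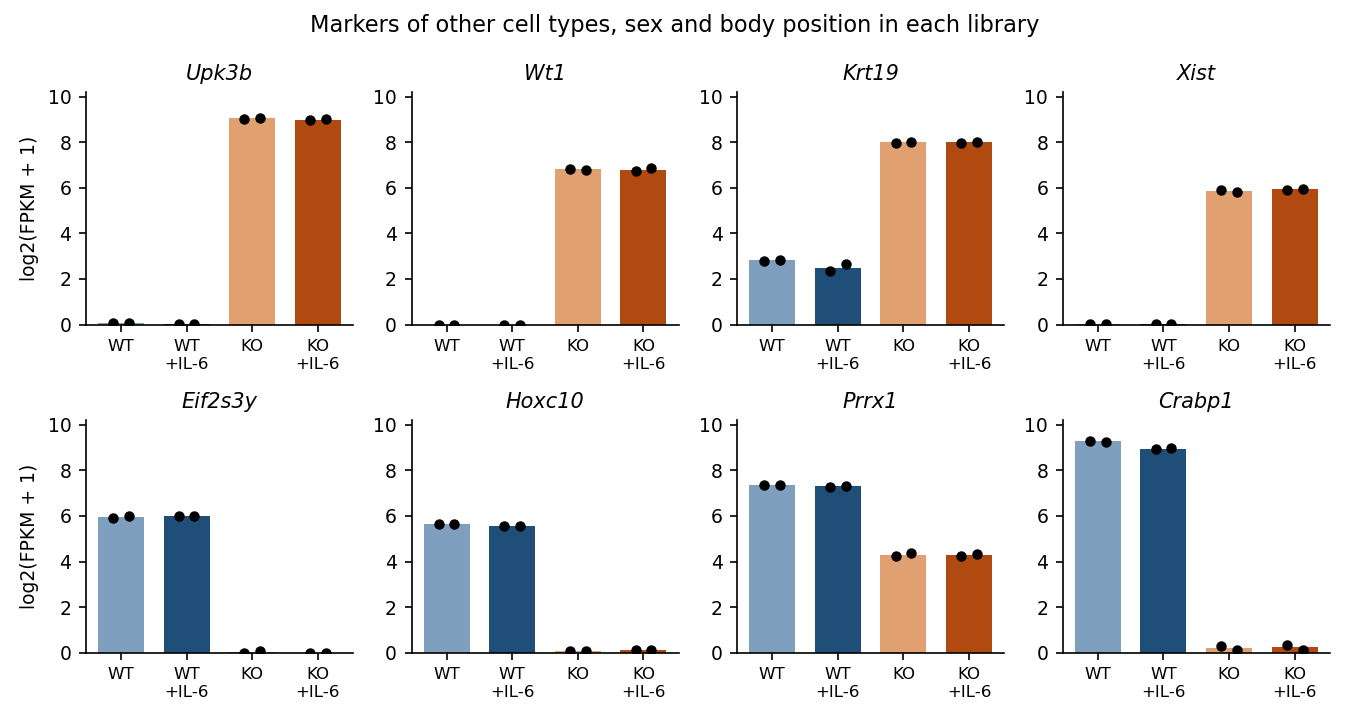
Level, as log2(FPKM + 1) on axes from 0, of 8 genes that mark tissue, sex or body position, with bars at the mean of 2 libraries and points for each library of untreated WT, WT with IL-6, untreated KO and KO with IL-6. Upk3b, Wt1 and Xist (56.9 FPKM in untreated KO) are at or near 0 in WT, Eif2s3y (60.8 FPKM in untreated WT), Hoxc10 and Crabp1 in KO, Krt19 is higher in KO and Prrx1 in WT.

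Of immune gene lists, 4 passed in untreated KO, where the tissue and sex markers also differed. STAT3 targets (21 lower, 9 higher of 33, list adjusted p = 0.0643), IL-6 receptor and JAK/STAT genes (13 and 5 of 22, 0.0691) and complement and acute-phase genes (9 and 6 of 16, 0.218) did not pass. Interferon-stimulated genes were lower in 40 of 43 (median -1.34, 40 adjusted over the list alone, list adjusted p = 1.25e-10, or 0.463 with an estimated correlation). The antiviral gene Oasl1 differed by -3.24 ± 0.095 and the GTPase gene Iigp1 by -3.18 ± 0.15. MHC class I genes were lower in 12 of 13 (13 adjusted over the list alone, list adjusted p = 0.000148, or 0.457 with an estimated correlation). The immunoproteasome gene Psmb9 differed by -2.01 ± 0.11; the H2 genes are near-identical and uncertain. Cytokines and chemokines were lower in 14 and higher in 3 of 21 (18 adjusted over the list alone, list adjusted p = 0.00168, or 0.421 with an estimated correlation). The neutrophil attractant gene Cxcl1 was lower (-6.75 ± 0.070) and the alarmin gene Il33 higher (4.69 ± 0.051). NF-kappaB targets were lower in 14 and higher in 2 of 17 (16 adjusted over the list alone, list adjusted p = 0.000398, or 0.307 with an estimated correlation). Ccl2, a monocyte attractant gene, was at 761.5 ± 12.9 and 84.9 ± 4.95 FPKM (-3.15 ± 0.053).

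Integrated stress response targets, among them Trib3, were higher in 20 and lower in 6 of 31 (26 adjusted over the list alone, list adjusted p = 0.00366, or 0.449 with an estimated correlation). Asns, for asparagine synthesis, was at 10.5 ± 0.538 and 53.1 ± 0.0150 FPKM (2.24 ± 0.046) and the proline synthesis gene Pycr1 at 2.17 ± 0.061. ER chaperones were higher in 16 and lower in 2 of 21 (18 adjusted over the list alone, list adjusted p = 0.00774, or 0.307 with an estimated correlation). The disulfide isomerase gene Pdia4 differed by 1.46 ± 0.041 and the ER stress factor gene Xbp1 by 1.38 ± 0.041. TGF-beta responses were higher in 12 and lower in 4 of 16 (16 adjusted over the list alone, list adjusted p = 0.0368, or 0.439 with an estimated correlation). Acta2 differed by 2.88 ± 0.052 and the matrix gene Tgfbi by -2.68 ± 0.042. Genes around Arid5a on chromosome 1 were higher in 18 and lower in 7 of 35 (25 adjusted over the list alone, list adjusted p = 0.133). The fibrillar matrix list had a median of 0.11 but a mean of -0.31 and a test pointing down (adjusted p = 0.825).

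LncRNAs higher in KO after Xist were Gm20186 (4.58 ± 0.16), 3110039M20Rik (4.02 ± 0.082), 1010001N08Rik (4.01 ± 0.12) and AI838599 (listed at 0 in WT, 12.3 ± 2.07 FPKM in KO), none with a known function. Lower were Gm48898 (-5.06 ± 0.069), Gm53 (-4.67 ± 0.074), 4930447F24Rik (-3.56 ± 0.092), the Hoxa11 antisense transcript Hoxa11os (-4.72 ± 0.063) and Hand2os1, upstream of the heart and limb gene Hand2 (-3.79 ± 0.19); antisense genes are uncertain, because no source says that fragments were counted by strand. Of 671 lncRNA genes, 415 passed (150 higher, 265 lower), or 61.85% against 71.43% of other genes. The odds ratio was 0.649 (95% confidence interval 0.551 to 0.764, adjusted p = 9.76e-07, Fisher's exact test). At 5 FPKM or more the odds ratio was in the other direction, 1.608 (unadjusted p = 0.0189, Fisher's exact test). In all, 9716 genes passed (70.96%; 4991 higher, 4725 lower), 1296 higher and 1173 lower by at least 2-fold. With equal totals 55.6% of calls were higher (5440 higher, 4343 lower). WT and KO libraries correlated at 0.8405 to 0.8503 on the log2 scale. The 20 genes with the highest mean over all 8 libraries held 10.8 to 11.5% of all FPKM in WT libraries and 7.63 to 7.88% in KO libraries.

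With IL-6 in both, most genes tested differed again. Lcn2 was at 215.0 ± 19.8 FPKM in WT and 0.635 ± 0.306 in KO (-7.06 ± 0.12, adjusted p = 4.38e-09), Saa3 at 594.5 ± 48.3 and 8.30 ± 0.704 (-6.0 ± 0.096), Il1rn, the IL-1 receptor antagonist gene, at 643.8 ± 2.54 and 1.75 ± 0.524 (-7.88 ± 0.19), and Cxcl1 at 176.7 ± 1.46 and 0.202 ± 0.0906 (-7.21 ± 0.070). Il6 differed by -1.59 ± 0.10 (adjusted p = 4.23e-06), Socs3 by -1.22 ± 0.060 (adjusted p = 1.06e-06), Map2k1 by -0.45 ± 0.037 and Map2k2 by -0.76 ± 0.093. Stat3 was higher in KO by 0.14 (adjusted p = 0.0123; 0.0657 without library 2 of WT with IL-6, 0.0599 without library 1 of KO with IL-6). Trf (1558 ± 10.4 FPKM in KO), Rhox5 (675.0 ± 22.1), Upk1b (334.8 ± 8.12), Gpm6a (285.2 ± 5.53), Lrrn4 (167.5 ± 4.73) and Tspan8 (131.4 ± 0.0460) were listed at 0 in WT, and Upk3b (8.95 ± 0.042) and Aldh1a1 (8.08 ± 0.049) were higher in KO. Cxcl5 (-9.17 ± 0.068), Crabp1 (-8.71 ± 0.084), Ly6a (-8.31 ± 0.23), Ccn5 (-8.06 ± 0.095), Penk (-7.65 ± 0.059) and the neuronal endosome gene Nsg1 (-7.67 ± 0.055) were lower. In all, 9813 genes passed (71.66%; 5046 higher, 4767 lower; 1406 and 1210 by at least 2-fold). With equal totals 58.7% of calls were higher (5799 higher, 4080 lower).

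STAT3 targets were lower in 23 and higher in 7 of 33 in KO with IL-6 (30 adjusted over the list alone, list adjusted p = 0.000215, or 0.324 with an estimated correlation). The metalloreductase gene Steap4 differed by -3.98 ± 0.080. IL-6 receptor and JAK/STAT genes were lower in 14 and higher in 3 of 22 (17 adjusted over the list alone, list adjusted p = 0.0123, or 0.465 with an estimated correlation). The IL-6 receptor gene Il6ra differed by -1.81 ± 0.068 and the kinase gene Jak1 by -1.12 ± 0.035. Complement and acute-phase genes were lower in 12 and higher in 4 of 16 (16 adjusted over the list alone, list adjusted p = 0.0207, or 0.484 with an estimated correlation). Immediate early genes were lower in 11 and higher in 3 of 17 (14 adjusted over the list alone, list adjusted p = 0.0181, or 0.324 with an estimated correlation). The shear-stress factor gene Klf2 differed by -2.93 ± 0.055. Contractile genes were higher in 8 and lower in 3 of 13 (11 adjusted over the list alone, list adjusted p = 0.0291, or 0.516 with an estimated correlation). Acta2 differed by 4.21 ± 0.052. Imprinted genes were higher in 9 and lower in 1 of 12 (11 adjusted over the list alone, list adjusted p = 0.0207, or 0.324 with an estimated correlation). The growth factor gene Igf2 differed by 3.35 ± 0.092.

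Of the 11 lists past the threshold without IL-6, all but TGF-beta responses (adjusted p = 0.0553) passed with it. Interferon-stimulated genes were lower in 40 and higher in 1 of 43 (41 adjusted over the list alone, list adjusted p = 2.33e-09, or 0.482 with an estimated correlation), and MHC class I genes in 11 of 13 (11 adjusted over the list alone, list adjusted p = 0.00064, or 0.482 with an estimated correlation). Cytokine and chemokine genes were lower in 17 and higher in 4 of 21 (21 adjusted over the list alone, list adjusted p = 0.000215, or 0.324 with an estimated correlation) and NF-kappaB targets in 15 and higher in 2 of 17 (17 adjusted over the list alone, list adjusted p = 7.78e-05, or 0.324 with an estimated correlation). Hox genes were lower in 25 and higher in 7 of 32 (32 adjusted over the list alone, list adjusted p = 6.54e-05, or 0.324 with an estimated correlation), and EMT regulators in 9 and higher in 2 of 11 (11 adjusted over the list alone, list adjusted p = 0.0207, or 0.324 with an estimated correlation). Sex-linked genes were lower in 4 and higher in 1 of 5, Xist being higher at 5.92 ± 0.059 (5 adjusted over the list alone, list adjusted p = 0.0369, or 0.465 with an estimated correlation). Integrated stress response targets were higher in 20 and lower in 9 of 31 (29 adjusted over the list alone, list adjusted p = 0.0236, or 0.482 with an estimated correlation), and ER chaperones in 14 and lower in 2 of 21 (16 adjusted over the list alone, list adjusted p = 0.0291, or 0.324 with an estimated correlation). Epithelial markers were higher in 8 and lower in 1 of 9 (9 adjusted over the list alone, list adjusted p = 0.000652, or 0.324 with an estimated correlation). The fibrillar matrix list had a median of 0.25 and a mean of -0.29, and proteases a median of -0.02, a mean of 0.28 and a test pointing up; neither list passed. LncRNAs at the ends were Gm20186 (5.08 ± 0.16), 3110039M20Rik (listed at 0 in WT, 15.2 ± 0.262 FPKM in KO), 1010001N08Rik (0 and 14.4 ± 1.32) and C430049B03Rik (3.94 ± 0.12) on the higher side, and Gm53 (-5.01 ± 0.074), Hoxa11os (24.3 ± 0.543 FPKM in WT, listed at 0 in KO), Hand2os1 (-3.94 ± 0.19), 4930447F24Rik (-3.43 ± 0.092) and Gm6093 (-3.34 ± 0.090) on the lower. Of 671 lncRNA genes, 422 passed (174 higher, 248 lower), or 62.89% against 72.12% of other genes (odds ratio 0.655, 95% confidence interval 0.556 to 0.773; adjusted p = 1.26e-06, Fisher's exact test; 1.123 at 5 FPKM or more). Across genes, the KO differences without and with IL-6 had r = 0.950 (rho 0.924), with 4436 genes higher and 4118 lower in both (1839.23 and 1644.93 by chance) and 51 called in opposite directions.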

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

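The tests of absent IL-6, receptor level, scaling, mixed cells, sex and transcript level were chosen only after the results were seen; those of genes too low in KO and of the tissue markers were written before their outcome was known. What singles out the results here is a tested difference between the IL-6 changes in KO and WT, found for 830 genes; each value is the KO change minus the WT change in log2(FPKM + 1), at adjusted p from 9.04e-05 (Timp1) to 0.0458 (Jun).

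Of study and cytokine signalling genes, the difference was -1.5 for Il6, -0.42 for Stat3, -0.80 for Socs3, -0.69 for Osmr, -1.30 for Timp1, -1.34 for Ptx3, -1.30 for Il13ra1, -1.16 for Nos2, -0.45 for Ccl2, -0.58 for Cxcl12, -0.96 for Cxcl2, -0.92 for Sod2, -0.43 for the NF-kappaB gene Nfkb1 and 0.57 for Vcam1. Acute-phase and secreted genes gave -1.54 for Saa3, -0.95 for Serping1, -2.51 for Serpina3n, -1.96 for Hp, -2.25 for Kng1, -1.89 for Slpi, -1.77 for Tnfsf11, -2.32 for U90926, -2.04 for Fabp4 and -2.11 for Gstt4, the last listed at 0 in KO. Growth factor genes gave -1.28 for Igfbp4, -1.70 for Angptl4, -1.52 for Ereg and -0.64 for Igfbp3. Genes of ERK output, immediate early and stress responses gave 1.04 for Ccnd1, -0.57 for Ier3, -0.82 for Dusp6, -0.90 for Junb, -0.41 for Jun, -0.46 for Asns, -0.71 for Cth, -0.54 for Ddit4 and -0.26 for Slc3a2. Metabolic, matrix and ribosomal genes gave -0.88 for Slc16a3, -0.43 for Aldoa, -0.77 for Vegfa, -0.32 for Tpi1, -1.20 for Mmp13, -0.58 for Plaur, -0.68 for Adamts5, -0.23 for Rps16 and -0.35 for Rps28.

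Genes lowered by IL-6 in WT and less or not in KO gave 1.33 for Acta2, 1.05 for Tagln, 0.96 for Ccn2, 0.60 for Ccn1, 1.5 for Col8a2, 1.35 for Dkk2, 2.06 for Hpgd, 1.91 for Gdf7 and 1.29 for Lrch2. Serpina3e-ps (2.60) and Srp54b (1.27), near-identical copies of other genes, are uncertain. LncRNAs gave 1.81 for Gm48898, 1.17 for Gm15867, 0.87 for 9330175E14Rik, 0.81 for C430049B03Rik, 0.81 for D030068K23Rik, -2.98 for Gm37055, -1.44 for Gm13293, -1.42 for Gm6093, -0.85 for Gm13415 and -0.74 for Gm42575. Some of these calls ended when a single library was left out: those of Rps16, Jun and Gm42575 ended without any 1 of the 8, those of Rps28, Slc3a2, Srp54b and 9330175E14Rik without any 1 of 7, those of C430049B03Rik, Cth and Ddit4 without any 1 of 6, that of Ccl2 without any 1 of 5, that of Gm15867 without any 1 of 3 and that of Tpi1 without either of 2. With a pseudocount of 0.1 the calls of Cxcl2 (adjusted p = 0.38), Gm13415 (0.267), Gm42575 (0.0986), Srp54b (0.082), Jun (0.0557) and C430049B03Rik (0.0518) ended. Quantile normalization ended those of Rps16, Rps28, Ccl2, Jun, Slc3a2 and Tpi1 (0.0503 to 0.155), and equal totals those of Jun (0.0603) and Rps16 (0.0548). No filter ended those of 9330175E14Rik, C430049B03Rik, Ccl2, Cth, Ddit4, Gm15867, Jun, Rps16, Rps28, Slc3a2 and Srp54b (0.0501 to 0.142), and no trend those of C430049B03Rik, Jun, Rps16, Rps28, Slc3a2 and Srp54b (0.0548 to 0.0959). The replicate block ended the calls of the same genes as no trend (0.061 to 0.0827). Gm37055 and Gm42575 were listed at 0 in KO, and the level of the short Gm37055 is uncertain. Serpina3n, U90926, Kng1, Fabp4, Gdf7, Hpgd and Gm48898 had KO means near 0 in both conditions. For these genes and Gstt4 the values mostly restate the WT change, and their sizes depend on the pseudocount.

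For the smaller IL-6 response in KO, absence of IL-6 from the KO cultures is argued against by 19 STAT3 targets past the threshold in KO adjusted over the list alone. The limit for absence, at most 2, was set after the results were seen. Genes too low in KO to register a change are not enough either: among 848 genes raised in WT with at least 5 FPKM in untreated KO, the median KO change was 0.101 times that in WT (0.030 against 0.298), under the 0.5 predicted. Less receptor might contribute, since Il6ra was lower in untreated KO by log2 -2.02 (adjusted p = 1.46e-07), with the shared receptor chain Il6st at -0.15. Loss of Arid5a, the biological explanation the design offers, could not be separated from the other differences between the cultures.

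The breadth of the genotype difference was not a matter of scaling, since at least 9752 genes passed between untreated KO and WT under 3 other scalings. Cells of the WT cultures mixed into the KO cultures are argued against by the Y-linked genes, at most 0.026% of WT there. WT cells of a female embryo would lack these genes, so the Y-linked test cannot speak to them. Female cells like those of the WT cultures are argued against by genes of other chromosomes. Crabp1 was at 482.5 to 631.7 FPKM in WT libraries and 0.0779 to 0.279 in KO libraries. Hoxc10 was at 46.3 to 49.0 and 0.0621 to 0.0985. Female WT cells of another tissue are not covered. Embryos of different sex stay open as a contribution. All 5 sex-linked genes passed, Xist on the opposite side from the Y-linked genes, but these genes prompted the test and do not show how much of the breadth sex accounts for. Cells of different tissue might contribute: 100.0% of tested mesothelial markers were higher in KO and 100.0% of tested limb markers lower, as written before they were looked up, though 3 of each had been seen in other lists. The limb and positional list fixed beforehand was mixed (12 lower, 7 higher of 21) and did not pass (adjusted p = 0.103). Arid5a loss, sex and tissue of origin all divide the libraries in the same way, so the share of each cannot be had from these libraries.

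For the Arid5a transcript left in KO, RNA from cells of the WT cultures is argued against by the same Y-linked genes. These were at most 0.026% of WT, against 26.9 to 35.7% for Arid5a. RNA of female WT cells would lack these genes. If such cells were like those of the WT cultures, the near absence of Crabp1 and Hoxc10 in KO argues against them too. Female WT cells of another tissue are not covered. An altered transcript from the targeted gene stays open, the uneven loss having prompted that test: Arid5a-205 was at 0.69% of WT while Arid5a-204 kept 41.30%. Arid5a-207 was at 2.83%, and Arid5a-208, below 1 FPKM in WT, at 148.23%. Which exons were removed was not given.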

How the results depend on the processing

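The scalings to the same total and by median ratios were chosen only after the results were seen, as were, for named genes alone, no trend, no filter, the 5 FPKM filter, a pseudocount of 5 and only the groups compared; the others were planned. Counts of genes past the threshold stayed within 1.5 times in every setting except those given here, and the cause was not tested except where fewer libraries, genes or fragments enter by construction. IL-6 in WT (2150): 938 with only the WT groups, 948 for transcripts, 1165 to 1774 with a library left out. IL-6 in KO (3): 7 with no filter, 5 at 5 FPKM or more, 0 with only the KO groups, 0 to 4 with a library left out. Difference between responses (830): 520 with no filter, 248 for transcripts, 383 to 523 with a library left out. A left-out library leaves its group with 1, assumed to vary like the other groups. With the replicate block the counts were 1696 (IL-6 in WT), 2 (IL-6 in KO), 9566 and 9685 (KO against WT without and with IL-6) and 564 (difference); the shared numbers do not pair the libraries (correlations of deviations -0.097 to 0.055). Lists past the threshold, 22, 11, 11, 16 and 18 in the order IL-6 in WT, IL-6 in KO, KO against WT without and with IL-6 and difference, were 0 with an estimated correlation in each; fry, which does not compare a list with other genes, gave 1 for IL-6 in KO and 37 and 40 for KO against WT. The odds ratio of lncRNA calls turned above 1 at 5 FPKM or more (164 lncRNA genes): 1.368, 1.608, 1.123 and 1.072 for IL-6 in WT, KO against WT without and with IL-6, and difference. By Fisher's exact test the unadjusted p was 0.105, 0.0189, 0.584 and 0.764 in that order. Only KO against WT without IL-6 was thus below 0.05. The correlation of the IL-6 changes across genes was -0.083 with a pseudocount of 0.1, and that of the KO differences 0.940. For named genes, a change of sign between results that both failed to pass was not counted as a reversal. Of 414 results for named genes none reversed; calls lost numbered 17 with quantile normalization, 16 without the trend, 27 without a filter, 8 and 2 with pseudocounts of 0.1 and 5, 12 with the block, 27 of 326 with only the groups compared, 9 with equal totals, 0 with median ratios and 18 to 29 with a library left out; most were at adjusted p above 0.01, such as Map2k1, B2m, Psmb9, Snhg6, Jun, Rps16 and Cebpd. Another deposited unit was not run, only FPKM being held, and alternatives for counts do not apply. AU021063 rests on 0 to 25.89 fragments per library.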

Other observations

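The choice of which lists and genes to set out here was made only after the results were seen; no further explanation was tested. Proliferation genes had medians of 0.02 with IL-6 in WT, -0.01 in KO and -0.06 between untreated KO and WT, where 9 were higher and 14 lower of 38 (23 adjusted over the list alone; list adjusted p = 0.563). Between untreated KO and WT (list adjusted p in brackets), basement membrane genes had a median of 0.87 (0.133), senescence and CDK inhibitor genes -0.32 (0.331), NRF2 targets -0.46 (0.132), limb and positional transcription factors -1.13 (0.103) and other nuclear lncRNAs 0.19 (0.746). Markers of other cells gave 0.31 for endothelium (6 genes tested), 0.62 for skeletal muscle (5), -0.74 for cartilage and bone (6) and -1.33 for neural crest and glia (5), none past the list threshold.

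Further mesothelial markers higher in untreated KO were Pkhd1l1 (5.43 ± 0.058), Nkain4 (4.43 ± 0.11), Gata4 (3.25 ± 0.086) and Muc16 (listed at 0 in WT, 4.68 ± 0.369 FPKM in KO), and further limb markers lower there were Tbx4 (-3.71 ± 0.078), Prrx2 (-3.63 ± 0.079), Msx2 (8.13 ± 0.00115 FPKM in WT, listed at 0 in KO) and Lmx1b (5.73 ± 1.05, likewise). Cdkn2a, the tumour suppressor locus often lost or raised in fibroblast culture and chosen after its value was seen, was at 1003 ± 58.0 FPKM in untreated WT and 387.6 ± 23 in untreated KO (-1.37 ± 0.055).

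Igfbp3 was the gene with the largest called IL-6 change in KO (0.86 ± 0.050), and at the same time its change was smaller than in WT (1.5 ± 0.050). C430049B03Rik, a lncRNA at 48.5 ± 2.32 FPKM in untreated KO, was at 4.69 ± 0.236 and 2.41 ± 0.694 FPKM in WT without and with IL-6. Lcn2 was at 0.191 ± 0.00980 and 0.635 ± 0.306 FPKM in KO without and with IL-6.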
